A study of Homo sapiens with 9 samples.

How the data were processed

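The series holds 9 polyA RNA-seq libraries of BJ fibroblasts, prepared with a TruSeq RNA kit per the labels. Groups were taken from the sample labels: control without RAS activation (1 library), senescent after RAS activation with a non-targeting hairpin (2 libraries), and RAS activation with knockdown of lncRNA-OIS1 (4 libraries, 1 per hairpin), p53 (1) or BRD7 (1). The analysis started from 1 deposited gene table, a signal per gene and library in which the authors had already normalised read counts. TopHat2, HTSeq and the build hg19 are named in the submitters' processing notes. Their roles, versions and gene annotation are not given in the sources used here. Quantile normalisation and a floor are known only from the name and the values of the table: all 9 columns hold the same set of values, each totals 14916466.5, no value is under 20, and 1375 of 13745 genes sit at 20 in each library (134 in all 9). Equal distributions remove any real difference in total RNA between groups, tie each value to a gene's rank, and hide the depth of each library, so neither depth nor counting error could be recovered. The highest value was 211606.6, and the 10 highest genes took 6.91% of the total.

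Values were used as deposited. The table pairs Ensembl identifiers with symbols. For 1030 genes it had no symbol, and 21 symbols had been turned into dates by a spreadsheet; 849 of these were filled from a table of gene names. No coordinates are printed, because the reference annotation supplied here is of another build than hg19. Genes that overlap or share sequence could exchange reads, and whether counting used strand is not given in the sources used here. LncRNA-OIS1 was not analysed here under that name.

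Tests were run in R 4.3.3 with limma 3.58.1. The linear model was fitted to log2 of the values, with no pseudocount since the floor keeps each value above 0, for 12481 genes whose highest value over the 9 libraries was at least 40. All 9 libraries entered 1 fit with 5 groups and 4 residual degrees of freedom, and variances were moderated with a trend on mean expression. The 3 groups of 1 library were assumed to vary like the 2 replicated groups, so a lone library has no replicate check of its own. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. With 4 libraries against 2, an exact permutation test of 1 gene cannot go below p = 0.0667, so limma alone was used. Fold changes of genes at the floor are lower bounds. Means are of the linear values, with their SD, while log2 changes compare means of log2 values.

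Comparisons were senescent against control, each knockdown against senescent, lncRNA-OIS1 knockdown against each other knockdown, and against control. The 18 gene lists, the rule for naming genes and the tests were fixed before the data were examined. Lists were RAS-MAPK output, inflammatory secretory factors, proteases and growth factors of the secretory phenotype, mitosis, DNA replication and E2F targets, p53 targets, senescence regulators, fibrillar extracellular matrix, contractile and TGF-beta response, interferon response, cholesterol synthesis, lysosome, unfolded protein response, glycolysis, and markers of epithelial, leukocyte, endothelial and mesenchymal cells. Each list with at least 3 members tested was tested with camera, using a preset correlation between genes of 0.01 and again an estimated one, with adjustment over the lists of a comparison. The median, mean and test of a list differed in sign in 15 cases, none of them called. Members were also counted after adjustment over the list alone. Named genes were 16 genes fixed in advance, the 10 largest rises and 10 largest falls among called genes whose libraries do not overlap between the groups, and per list up to 2 called members in each direction. Genes outside this rule were named after their values were seen, whether or not the text says so again. Some genes that entered the fits and lists are not reported here.

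Similarity of the 3 knockdowns was measured as a correlation, covariance and share of equal signs across genes, beside 50 simulations of unchanged groups that share the senescent libraries, and again with a separate senescent library for each knockdown. The share of RAS-changed genes that moved back was set beside simulated values in the same way. The fit was tested on simulated data with 200 of 12481 genes changed by known folds. The changed genes lay well above the floor, and noise was drawn independently for each value from the moderated variances. The rates therefore need not hold for the real data. Recovery of 2-fold, 4-fold and 8-fold changes was 0%, 85% and 95% for senescent against control, 66.5%, 91.5% and 99% for lncRNA-OIS1 knockdown, 0%, 86% and 94.5% for p53 knockdown, and 9%, 85.5% and 95% for BRD7 knockdown, each against senescent. Alternatives were pseudocounts of 10 and 50, no filter, a filter on a mean of at least 80, median-of-ratios scaling of the deposited values, variance moderation without trend or with robust estimation, a minimum of 2-fold, a replicate block, and leaving out each replicate of the 2 replicated groups in turn.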

Results

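RNA was measured in BJ cells, human fibroblasts immortalised with telomerase, in which an oncogenic form of RAS can be switched on so that the cells enter senescence, a lasting arrest of proliferation. The 9 polyA RNA-seq libraries fall into 5 groups. A control without RAS activation carried a non-targeting hairpin and had 1 library. The senescent group had RAS activated and held 2 libraries, each with a different non-targeting hairpin. LncRNA-OIS1, a long non-coding RNA, was knocked down before RAS activation in 4 libraries, each with its own hairpin. p53 and BRD7, a bromodomain protein, were knocked down before RAS activation in 1 library each. The labels give 14 days of 4-OHT for all 9 libraries, although the design text calls the control untreated. Each value was a normalised read count, and the table holds 13745 genes. The deposited normalisation gave every library the same set of values, with a total of 14916466.5, a median of 340.1 and a floor of 20 at which 10% of genes sat in each library. Sequencing depth is therefore unknown, and no counting error can be given. The libraries of a group carried different hairpins per the labels, which do not say whether they came from separate experiments. The p-values measure the spread between these libraries, which mixes differences between hairpins and cultures with technical ones. Genes at the floor in all senescent and lncRNA-OIS1 libraries had no such spread, among them SULF1, ANO3, PREX2, GPR133, CNN1, PDGFA and PTPRC. Their p-values rest on the variance that moderation assigns and on the single control library.

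BRD7 (ENSG00000166164) stood at 94.6 in its knockdown library against 583 ± 65.1 (SD, n = 2) in the senescent libraries, 16.2% of the senescent mean (log2 −2.62, SE 0.15, adjusted p = 0.0461), and between 536.6 and 695.3 elsewhere. LncRNA-OIS1 was not analysed here under that name, so its knockdown was not checked. DPP4, which encodes a cell-surface protease, had 1230.2 in the control, 2025 ± 36.8 in the senescent libraries, 361.4 with p53 knockdown and 1053.6 with BRD7 knockdown. With lncRNA-OIS1 hairpins DPP4 had 1477 ± 635 (n = 4). Replicate 3, at 2390, was above both senescent libraries, and replicates 1, 2 and 4 were below both (1344.6, 1248.8 and 922.9). No comparison called DPP4 (adjusted p = 0.386 against control, and 0.436, 0.0605 and 0.492 for the knockdowns against senescent). HRAS was highest in the control library at 26556.6 and stood at 11686 ± 516 in the senescent libraries (adjusted p = 0.0507). GLB1, the lysosomal β-galactosidase whose activity is a common stain for senescent cells, stood at 1389.8 in the control and 1227 ± 76.8 in the senescent libraries (adjusted p = 0.3). Its mean with lncRNA-OIS1 hairpins was 1044 ± 33.7 (adjusted p = 0.163).

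**Figure D1:**
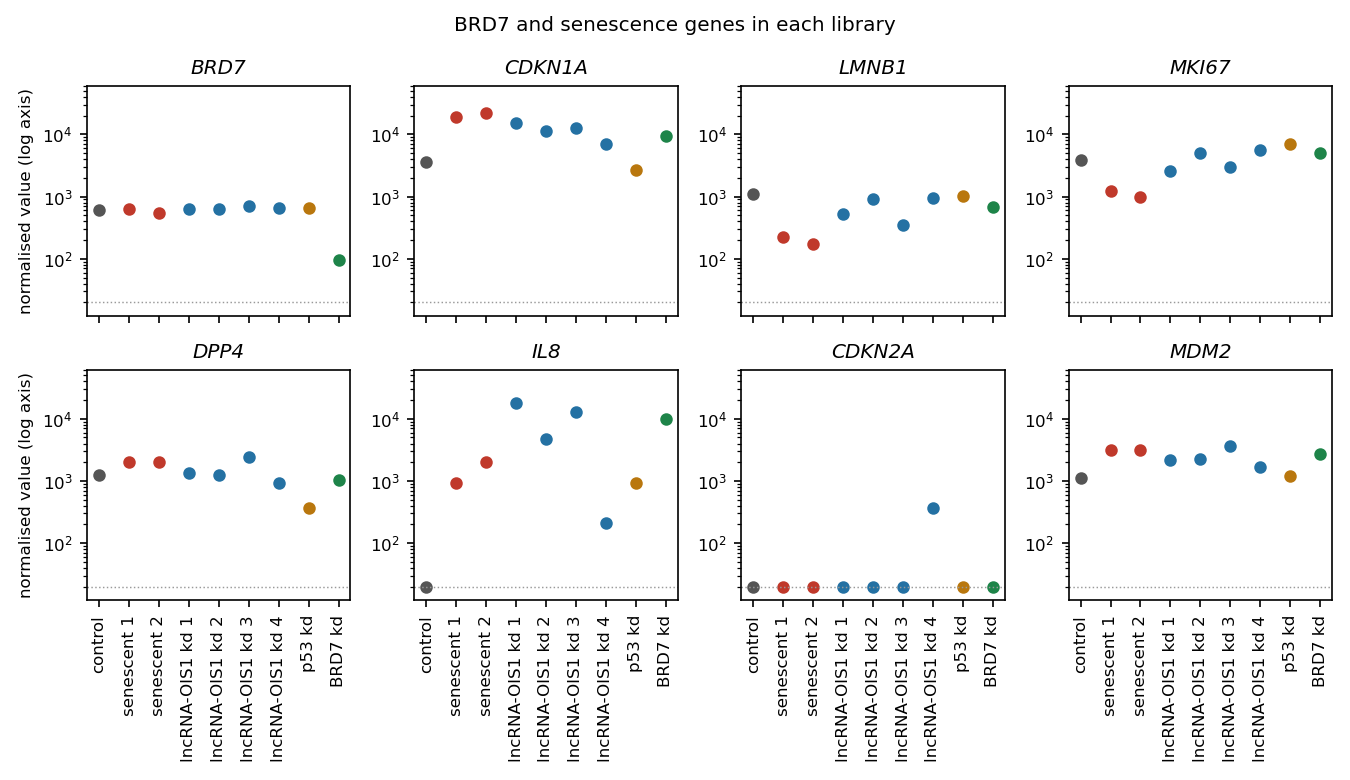
Normalised read count (log axis, floor at 20) of 8 of the genes fixed in advance, with 1 point per library coloured by group. BRD7 is lowest in the BRD7 knockdown library at 94.6, and CDKN2A is above the floor in lncRNA-OIS1 replicate 4 at 362.3.

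The control library and lncRNA-OIS1 replicate 4 stood apart from the rest. In the control, 490 genes were over 2-fold above every other library and 315 over 2-fold below. In lncRNA-OIS1 replicate 4 these counts were 300 and 224, and 133 of the 300 genes were at the floor in all 8 other libraries. Among them was CDKN2A, the locus of p16 and ARF, at 362.3 in replicate 4 and at the floor in the other 8. VCAN, a matrix proteoglycan named here after its values were seen, stood at 2135 in replicate 4 and at 142.3 or less elsewhere. The remaining 7 libraries had at most 27 such genes in either direction. Across genes, the senescent libraries correlated at r = 0.996, lncRNA-OIS1 replicates 1 to 3 at 0.981 to 0.982, and replicate 4 with those 3 at 0.92 to 0.935. The BRD7 knockdown library was the closest to replicate 2 (0.989) and to replicate 3 (0.982), and replicate 2 the closest to p53 knockdown (0.982). Replicates 1 to 3 were thus not set apart from the other knockdown libraries by r. Genes are not independent replicates, so these r values only describe the libraries. The first principal component (36.4% of the variance) separated the control from the RAS libraries, and the second (29.2%) separated replicate 4.

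**Figure D2:**
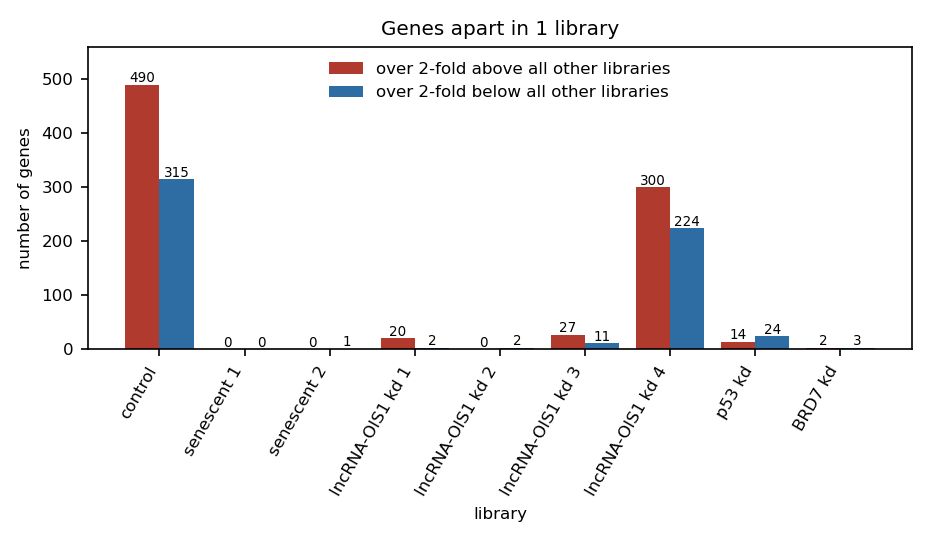
Number of genes whose value in a library is over 2-fold above (or below) its value in every other library, for each of the 9 libraries. The control (490 and 315) and lncRNA-OIS1 replicate 4 (300 and 224) stand apart.

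The comparison of senescent with control libraries asked what RAS activation did to expression. MMP1, an interstitial collagenase, stood at 361 in the control and 47846 ± 3570 (n = 2) in the senescent libraries, 132-fold higher (log2 7.05, SE 0.93, adjusted p = 0.0119). STC1, a secreted glycoprotein, rose from 672.7 to 59081 ± 9580 (log2 6.45, adjusted p = 0.00211). TRPA1, a cation channel, was at the floor in the control and rose at least 120.5-fold. PKIA rose at least 64.1-fold, and TMEM158, TM4SF1, DOCK4, SERPINB2, SPP1 and LINC00973 completed the 10 largest rises, with log2 changes of 5.14 to 5.65. CHRM2, a muscarinic receptor, fell most, from 5921.4 to 36 and 21.1 (log2 −7.75). The matrix proteoglycan DCN fell from 11040 to 69.95 ± 2.48 (log2 −7.30, adjusted p = 0.00182). ALDH1A1, a retinaldehyde dehydrogenase, fell from 18967 to 165 ± 35.5 (log2 −6.86). SULF1, ANO3, PREX2, FAM65B and GPR133 were at the floor in both senescent libraries and at least 61.8-fold lower than in the control. FAM65B apart, these had no spread of their own in the replicated groups. LMCD1 and SYPL2 had log2 changes of −5.96 and −5.93. CDKN1A, the p53-induced inhibitor p21, rose from 3578.4 to 20559 ± 2565 (log2 2.52, adjusted p = 0.0251), and CDKN2B, the inhibitor p15, from 39 to 277 ± 38.1 (log2 2.82, adjusted p = 0.0396). By limma, 1878 of 12481 genes changed, 992 higher and 886 lower in the senescent libraries. The control had no replicate and was assumed to vary like the replicated groups, and the count was 137 or 124 without senescent replicate 1 or 2, 1136 without lncRNA-OIS1 replicate 2 and 3704 without replicate 4, whose spread enters every test. In the fit without replicate 4, 1861 of the 1878 calls remained. Replicate 4 enters only the spread in this comparison, so log2 changes and signs were bound to stay the same. Falls outnumbered rises among the calls of at least 2-fold (670 and 551), with median-of-ratios scaling (1036 and 796) and without lncRNA-OIS1 replicate 2 (575 and 561). They also did so without senescent replicate 1 or 2.

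**Figure D3:**
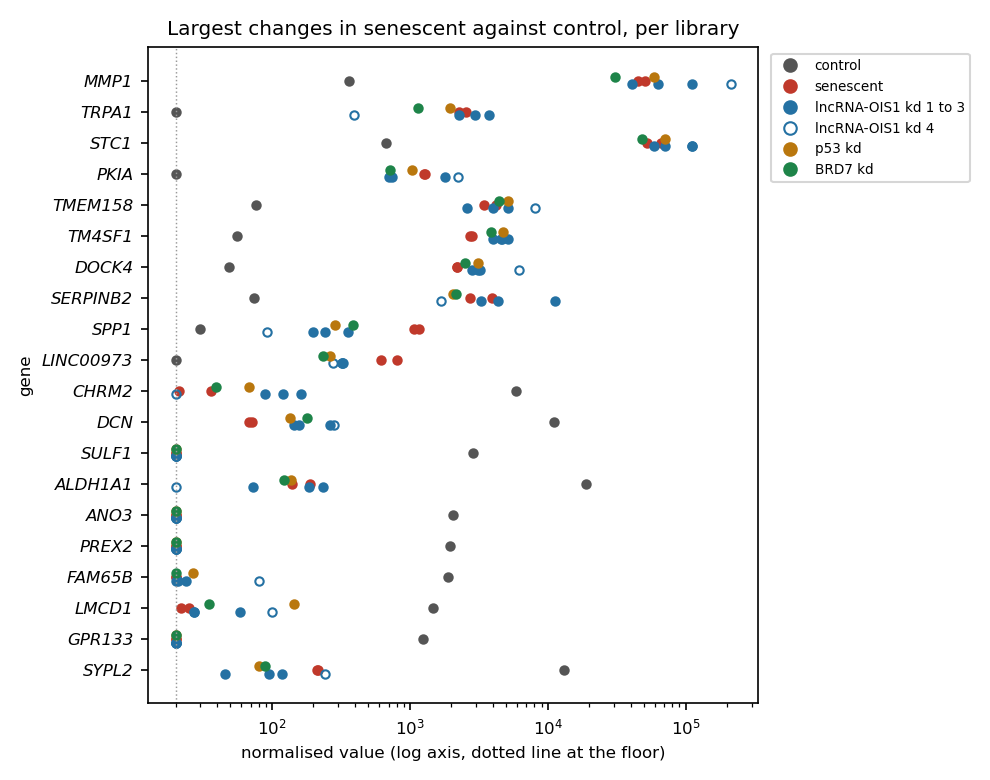
Normalised read count (log axis, floor at 20) in each of the 9 libraries of the genes with the largest changes between senescent and control libraries. MMP1 has 361 in the control and 47846 on average in the senescent libraries, and DCN 11040 in the control and 69.95.

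The rises and falls after RAS activation were grouped by the 18 lists fixed before the data were examined. Of 24 genes of RAS-MAPK output, 10 rose and 1 fell (13 and 1 adjusted over the list alone). The pathway's feedback inhibitors SPRY2 (283.4 to 4024 ± 112, log2 3.83) and DUSP4 (log2 3.64) rose most, and the transcription factor ETS1 fell by 0.54. The median log2 change was 0.95 (camera adjusted p = 8.41e-05, and adjusted p = 0.285 with an estimated correlation). Of 34 p53 targets, 12 rose and none fell (23 and 1 adjusted over the list alone), with a median of 1.26 (adjusted p = 9.64e-07, and 0.508 with an estimated correlation). PMAIP1, a pro-apoptotic BCL2-family gene, rose by log2 3.81, and E2F7, a repressor of the cell cycle, by 3.72. MDM2, the p53 ubiquitin ligase, had 1095.2 in the control and 3160 ± 46.2 in the senescent libraries (adjusted p = 0.0667, and 0.0439 without replicate 4). Senescence regulators moved both ways: 3 of 29 rose and 7 fell (5 and 12 adjusted over the list alone; median −0.57, adjusted p = 0.012, and 0.285 with an estimated correlation). The chromatin protein gene HMGA2 rose by log2 2.87, while the CDK inhibitor genes CDKN2C and CDKN1B fell by 3.78 and 2.07. Without replicate 4, 20 p53 targets rose and 1 fell, and 5 senescence regulators rose and 11 fell.

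Proliferation genes were lower as a group in the senescent libraries. Of 38 mitosis genes 5 fell and none rose (0 in either direction adjusted over the list alone), with a median of −1.08 (adjusted p = 4.93e-08, and 0.508 with an estimated correlation). KIF20A, a mitotic kinesin, fell from 1267 to 303 ± 64.8 (log2 −2.08), and ASPM, a spindle protein gene, by 1.67. Of 41 DNA replication and E2F target genes 6 fell and 1 rose (19 and 1 adjusted over the list alone; median −1.12, adjusted p = 1.98e-08, and 0.508 with an estimated correlation). The helicase gene MCM6 fell by 2.44, E2F2 was at the floor in both senescent libraries, at least 5.84-fold lower, and the cyclin gene CCNE1 rose by 1.69. Without replicate 4, 10 of the replication and E2F targets fell. MKI67, CCNA2 and the nuclear lamina gene LMNB1 had lower values in both senescent libraries than in the control and were not called. Their senescent means were 1102 ± 183, 349.8 ± 46.7 and 199.6 ± 34.9 against 3913.6, 897.6 and 1083.3 (adjusted p = 0.069, 0.0671 and 0.0581). Without replicate 4, MKI67 (adjusted p = 0.0473) and LMNB1 (0.0491) were called.

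Genes of the fibroblast matrix and contractile apparatus were lower too. Of 31 fibrillar extracellular matrix genes 10 fell (16 without replicate 4) and none rose (14 and 0 adjusted over the list alone; median −1.35, adjusted p = 9.64e-07, and 0.285 with an estimated correlation). LUM, the proteoglycan lumican, fell from 20683 to 449 ± 75.7 (log2 −5.53). In the contractile and TGF-beta response list 7 of 15 fell and none rose (11 and 0 adjusted over the list alone; median −1.71, adjusted p = 9.64e-07, and 0.285 with an estimated correlation). LMOD1, an actin nucleator, fell by 5.08, and CNN1, or calponin, was at the floor in both senescent libraries, at least 27.3-fold lower. Among 33 interferon response genes 8 fell and none rose (10 and 0 adjusted over the list alone; median −0.53, adjusted p = 0.00028, and 0.508 with an estimated correlation), led by IFIT1 (log2 −2.97) and IFIT2 (−2.29).

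Secretory factor lists did not shift as groups. Among 20 inflammatory secretory factors 1 fell, also when adjusted over the list alone: the chemokine CXCL12, at 426.8 in the control and at the floor in both senescent libraries (adjusted p = 0.00182). The list's median was 0.07 and its mean 0.56, while the test pointed down (adjusted p = 0.947). IL8 (CXCL8), a neutrophil chemokine, was at the floor in the control and at 931.6 and 2021.6 in the senescent libraries (adjusted p = 0.171). IL1B had 23.2 in the control and 1035 and 3344.9 in the senescent libraries (adjusted p = 0.258), IL1A had 20 against 34.4 and 69.2 (adjusted p = 0.43), and IL6 was at the floor in all 3. Without replicate 4, IL8 (adjusted p = 0.0184), IL1B (0.0226) and CXCL1 (0.0445, named after its values were seen) were called higher, and the list still did not pass (adjusted p = 0.793). Of 33 proteases and growth factors, 7 rose, with MMP1 and STC1 in front, and 3 fell, among them PDGFA and TGFB2 (11 and 7 without replicate 4; 11 and 3 adjusted over the list alone; adjusted p = 0.529). The mesenchymal and fibroblast markers had 2 of 17 higher (the ectonucleotidase NT5E by log2 4.02, and MME) and 5 lower, among them FAP (−5.51) and the cadherin CDH2 (−4.57), with the same counts adjusted over the list alone (adjusted p = 0.371; 4 higher and 6 lower without replicate 4). The glycolysis list had 3 of 20 higher, also adjusted over the list alone, led by PDK1 and HK2 (adjusted p = 0.117), and the unfolded protein response list 3 of 22, led by SDF2L1 and MANF (2 adjusted over the list alone; adjusted p = 0.273). Without replicate 4 the latter had 6 higher and 3 lower. In the lysosome list GLA rose and 3 of 33 fell, among them GUSB and NAGLU (1 and 3 adjusted over the list alone; adjusted p = 0.437), and in the cholesterol synthesis list 1 of 22 fell, INSIG1, also adjusted over the list alone (median 0.06, mean −0.11, test down, adjusted p = 0.604). Without replicate 4 this list had 2 higher and 4 lower over all genes, and 2 and 7 adjusted over the list alone.

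Markers of other cell types were few. Of the 3 epithelial markers tested 0 were called and 1 was lower adjusted over the list alone (adjusted p = 0.307). KRT18, the most abundant, had 3073.7 in the control and 1617.8 and 1344.6 in the senescent libraries. Among 4 leukocyte markers PTPRC was called, at 156.6 in the control and at the floor in the other 8 libraries (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.604). The 1 endothelial marker tested, TIE1, had 266.9 in the p53 knockdown library and 129.1 or less in the other 8.

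**Figure D4:**
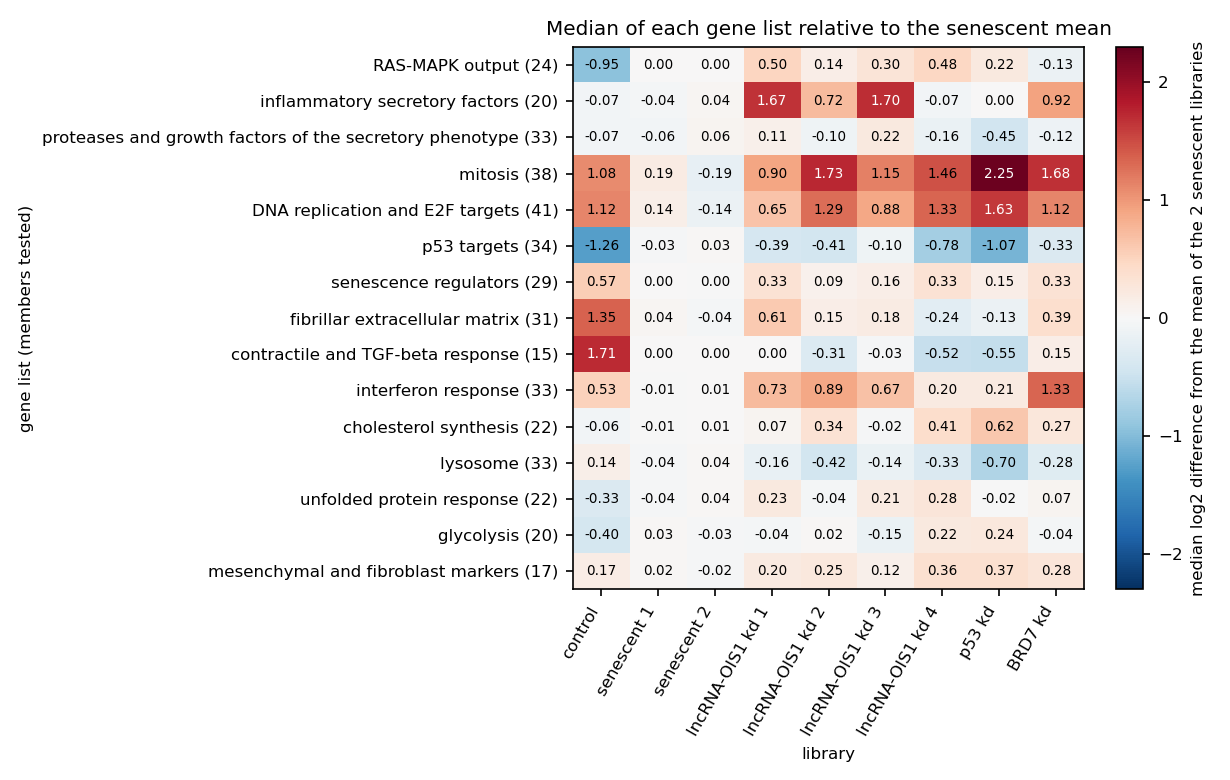
Median log2 change of each fixed gene list in each of the 9 libraries, relative to the mean of the senescent libraries. Mitosis medians are above 0 in the control (1.08) and in all 6 knockdown libraries (0.90 to 2.25), and inflammatory secretory factors reach 1.67 and 1.70 in lncRNA-OIS1 replicates 1 and 3 against −0.07 in replicate 4.

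Knockdown of lncRNA-OIS1 was compared with the senescent libraries to see which RAS-linked changes it altered. Proliferation genes were higher as groups in the knockdown libraries. The 38 mitosis genes had a median log2 change of 1.30, with 38 of 38 above 0, and 37 passed adjusted over the list alone (camera adjusted p = 4.02e-23, and 0.346 with an estimated correlation). The 41 DNA replication and E2F target genes had a median of 1.02, and adjusted over the list alone 35 were higher and 1, CCNE1 (named after its values were seen), lower (adjusted p = 8.78e-18, and 0.346 with an estimated correlation). Over all genes 0 members of either list were called. The estimated correlation between genes was 0.858 for the mitosis list and 0.678 for the replication and E2F list, in every comparison of this fit. Members of each list are therefore not separate evidence, and counts of members only describe the list. FOXM1, a transcription factor of mitotic genes named here after its values were seen, had 1069 ± 282 (n = 4) against 319 ± 72.6 (n = 2; adjusted p = 0.0788). MKI67 had 4060.5 ± 1522 against 1102 ± 183 (adjusted p = 0.0856), and CCNA2 1006 ± 276 against 349.8 ± 46.7 (adjusted p = 0.0824). LMNB1 had 526.3, 922.7, 347.1 and 949.6 against 224.3 and 174.9 (adjusted p = 0.119). CDKN1A had 11550 ± 3532 against 20559 ± 2565 (adjusted p = 0.188), and MDM2 2425 ± 855 against 3160 ± 46.2 (adjusted p = 0.443). The p53 target list was lower, with 28 of 34 below 0, a median of −0.48 and 0 members called over all genes or adjusted over the list alone (adjusted p = 0.00122, and 0.557 with an estimated correlation).

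Interferon and inflammatory genes were also higher with lncRNA-OIS1 hairpins, again with 0 members called over all genes in the fit to all 9 libraries. The interferon response list had a median of 0.66 and 6 of 33 members higher adjusted over the list alone, among them the antiviral genes OAS3 and IFIH1, both named after their values were seen (adjusted p = 1.95e-07, and 0.346 with an estimated correlation). Without replicate 4 the median was 0.73, with 4 members called over all genes and 17 adjusted over the list alone (adjusted p = 3.02e-09, and 0.441 with an estimated correlation). OAS3 had 652 ± 95.9 against 181 ± 27.8 (adjusted p = 0.0788). Inflammatory secretory factors had a median of 0.88 (adjusted p = 0.00304, and 0.537 with an estimated correlation) with unequal libraries: 1.67, 0.72 and 1.70 in replicates 1 to 3 and −0.07 in replicate 4. IL8 had 17615.8, 4733.9 and 12902.8 in replicates 1 to 3, 212 in replicate 4 and 931.6 and 2021.6 in the senescent libraries (adjusted p = 0.682). IL1B showed 12902.8, 4790.4 and 18474.2, then 60.1 in replicate 4, against 1035 and 3344.9 (adjusted p = 0.905). PTGS2, the prostaglandin synthase COX-2, named after its values were seen, was the member that passed adjusted over the list alone, at 9434 ± 3437 against 1894 ± 63.7 (adjusted p = 0.0788 over all genes). Without replicate 4 the inflammatory median was 1.32, with 1 member called over all genes and 4 adjusted over the list alone (adjusted p = 2.82e-05, and 0.441 with an estimated correlation).

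Smaller shifts were found in 5 more lists. RAS-MAPK output had a median of 0.47 and 2 members higher adjusted over the list alone (adjusted p = 0.00129, and 0.346 with an estimated correlation), and senescence regulators 0.19 and 3 members (adjusted p = 0.0105, and 0.346 with an estimated correlation). CDKN2C, named after its values were seen like INSIG1 and GLA below, was among the 3, at 232 ± 33.2 against 55.4 ± 4.74 (adjusted p = 0.0788). Without replicate 4, 3 senescence regulators and 1 gene of RAS-MAPK output were called over all genes. Cholesterol synthesis had 0.20 and 2 members, among them INSIG1 (adjusted p = 0.00304, and 0.557 with an estimated correlation). It had 0.12 and 1 member without replicate 4 (adjusted p = 0.0328, and 0.733 with an estimated correlation). The lysosome list was lower at −0.24, with GLA lower adjusted over the list alone (adjusted p = 0.00235, and 0.346 with an estimated correlation). The unfolded protein response list had 0.13 and 0 members (adjusted p = 0.0497, and 0.557 with an estimated correlation), and passed no longer without replicate 4 (adjusted p = 0.0617). Mesenchymal markers (adjusted p = 0.051, with 2 members higher adjusted over the list alone), contractile genes (0.142), matrix genes (0.282), proteases and growth factors (0.482), glycolysis (0.54), leukocyte (0.957) and epithelial markers (0.977) did not pass. Matrix genes passed without replicate 4, with members going both ways (1 higher and 1 lower over all genes, 9 and 2 adjusted over the list alone; median 0.25, adjusted p = 0.0328, and 0.614 with an estimated correlation).

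Gene by gene, limma called 0 of 12481 genes between lncRNA-OIS1 knockdown and senescent libraries (2805 at an unadjusted p under 0.05, lowest adjusted p = 0.0788). With no filter there were 57, 22 higher and 35 lower, of which 16 were genes that the filter removes. In simulated data of the same size 66.5% of genes changed 2-fold and 91.5% of those changed 4-fold were recovered in this comparison. The simulation changed only genes well above the floor and drew independent noise, so these rates do not give the power of the real comparison. In the fit without replicate 4, which was looked into because of what the data showed, 164 genes were called, 80 higher and 84 lower. FST, the activin antagonist follistatin, then led the rises at 479.9 ± 40 (n = 3) against 69.1 ± 0.99 (log2 2.79, adjusted p = 0.0138). SPHKAP, CDKN2C, OAS3, TNFAIP8, the cytokine-signalling inhibitor SOCS1, CADPS2, NTSR1, OLFML2B and DCHS1 followed, at log2 1.67 to 2.25. The gap-junction gene GJA5 fell most (log2 −2.39, adjusted p = 0.0389), followed by NTNG1 and CPA4, and LOX, the collagen crosslinker lysyl oxidase, fell from 4910.4 ± 36.3 to 1631 ± 242 (log2 −1.60). In replicate 4 itself FST stood at 994.1 and GJA5 at the floor, on the side of the other 3 hairpins, while NTNG1 stood at 635.4, CPA4 at 100.7 and DCHS1 at 340.8, beyond the senescent values on the other side. Leaving out replicate 2 gave 1 call, INSIG1.

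Knockdown of p53 was compared with the senescent libraries in the same way. Mitosis genes rose: 22 of 38 were called over all genes and 38 adjusted over the list alone, with a median log2 change of 2.25 (adjusted p = 7.63e-24, and 0.456 with an estimated correlation). CENPA, the centromeric histone, had 325.3 against 50.5 ± 22.8 (log2 2.77, adjusted p = 0.0495), and FOXM1 1830.3 against 319 ± 72.6 (log2 2.54). PLK4, a centriole duplication kinase, rose by log2 2.84 (adjusted p = 0.0467), and SMC4, CEP55, CDC25C, EME1, BLM and NMI by 2.48 to 2.62. Of the DNA replication and E2F targets, 10 of 41 rose, led by CCNA2 (log2 2.53, adjusted p = 0.0467) and GINS2 (1.99), and adjusted over the list alone 37 were higher and 1 lower (median 1.63, adjusted p = 2.4e-17, and 0.456 with an estimated correlation). MKI67 had 6931.1 against 1102 ± 183 (adjusted p = 0.0556, and 0.0383 without replicate 4), and LMNB1 1015.8 against 199.6 ± 34.9 (adjusted p = 0.0922). Genes that p53 activates fell: 5 of 34 p53 targets over all genes and 19 adjusted over the list alone, with a median of −1.07 (adjusted p = 1.84e-09, and 0.456 with an estimated correlation). The antiproliferative gene BTG2 was at the floor, at least 11.6-fold lower, SPATA18 fell by 3.10 on the log2 scale, and CDKN1A fell from 20559 ± 2565 to 2721.1 (log2 −2.91, adjusted p = 0.0467). MDM2 had 1214.9 against 3160 ± 46.2 (adjusted p = 0.117). WFDC1, NAALADL2, INSC, HIST2H2BE, CYFIP2 and IDUA were also among the 10 largest falls, at log2 −3.11 to −2.50. Without replicate 4, 27 replication and E2F targets rose and 16 p53 targets fell.

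Other lists moved less with p53 knockdown. Lysosome genes fell as a list (median −0.70, camera adjusted p = 1.31e-07, and 0.456 with an estimated correlation). Over all genes 4 of 33 were lower, with ARSA (log2 −1.62) and GAA (−1.51) in front. Adjusted over the list alone 14 were lower and 1 higher. Without replicate 4, 15 were called lower and 1 higher over all genes. Cholesterol synthesis had a median of 0.62 and 0 members called, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 9.47e-05, and 0.546 with an estimated correlation). Without replicate 4, 3 of its members were called higher and 1 lower over all genes. The senescence regulators did not shift as a list (3 up and 2 down, 8 and 3 adjusted over the list alone, 6 up and 3 down over all genes without replicate 4; adjusted p = 0.309), but CDKN2C (log2 2.35) and the chromatin protein gene HMGB1 (1.58) rose. The remaining lists did not pass, with adjusted p between 0.117 and 0.905, and ETS1 rose while LOX and ACTA2 fell in them. Without replicate 4 these lists did not pass either. Higher and lower calls were then 4 and 1 for interferon, 3 and 0 for RAS-MAPK, and 3 and 1 for glycolysis genes. They were 1 and 5 for contractile genes and 0 and 4 for matrix genes. Proteases and growth factors, and mesenchymal markers, had 2 and 1 each. The unfolded protein response list had 2 higher, inflammatory factors 1 higher and leukocyte markers 1 lower. Inflammatory factors had a mean of −0.03 while the test pointed up (adjusted p = 0.604), with IL8 at 939.3 and IL1B at 465.8. In all, 479 genes changed, 283 higher and 196 lower, and for eBayes without trend 2, both lower. The single p53 library had no replicate, and the count was 0 without lncRNA-OIS1 replicate 1, 2 or 3. It was 2146 without replicate 4 (1045 higher and 1101 lower), where all 479 calls remained. Replicate 4 enters only the spread here, so log2 changes and signs were bound to stay the same. The called genes named for this comparison had, NAALADL2 (0.0388) apart, adjusted p of 0.0467 to 0.0495. In simulated data, with the limits given above, 0% of 2-fold and 86% of 4-fold changes were recovered here.

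With BRD7 knockdown, interferon and proliferation lists were higher than in the senescent libraries. The interferon response list had 33 of 33 members above the senescent mean, with a median of 1.33 and 13 members higher adjusted over the list alone (adjusted p = 3.98e-14, and 0.331 with an estimated correlation). IFIT1 stood at 567.9 against 110 ± 9.83 and OAS3 at 896.2 against 181 ± 27.8, both named after their values were seen (adjusted p = 0.204 and 0.196). The mitosis list had a median of 1.68 with 37 of 38 higher adjusted over the list alone (adjusted p = 2.38e-29, and 0.331 with an estimated correlation), and the DNA replication and E2F list 1.12 with 32 of 41 (adjusted p = 3.36e-21, and 0.331 with an estimated correlation). MKI67 had 5027.6 against 1102 ± 183 (adjusted p = 0.201), LMNB1 682.3 against 199.6 ± 34.9 (0.312) and CDKN1A 9405.6 against 20559 ± 2565 (0.361). Inflammatory factors had a median of 0.92 with 0 members passing adjusted over the list alone (adjusted p = 0.0154, and 0.598 with an estimated correlation), with IL8 at 9812.7 and IL1B at 5606.9. Cholesterol synthesis (0.27, 2 members; adjusted p = 0.00222, and 0.563 with an estimated correlation), matrix genes (0.39, 0 members; 0.0154, and 0.563) and senescence regulators (0.33, 3 members; 0.0162, and 0.331) were higher, and p53 targets (−0.33, 0 members; 0.0154, and 0.764) and lysosome genes (−0.28, 0 members; 0.0162, and 0.563) lower, with members counted as adjusted over the list alone and the second p with an estimated correlation. Without replicate 4 cholesterol synthesis had 4 higher and 1 lower in this count, and senescence regulators 4 and 2. Mesenchymal markers had an adjusted p of 0.0771 (0.0387 without replicate 4, and 0.471 with an estimated correlation) and the other lists 0.35 to 0.997. BRD7 was the 1 gene called (1735 at an unadjusted p under 0.05), and it was not called with pseudocounts of 10 or 50 or for eBayes without trend. With no filter there were 30 calls, 24 of them genes that the filter removes. No gene was called without either senescent library or without lncRNA-OIS1 replicate 1, 2 or 3. Without replicate 4 there were 8, with IL1R1, the interleukin-1 receptor, higher at 2564.3 against 896 ± 24.8 (log2 1.52, adjusted p = 0.0473) and CPA4 at the floor, at least 4.53-fold lower.

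The lncRNA-OIS1 knockdown was then set directly against the other knockdowns. Against p53 knockdown 1 gene was called by limma (1329 at an unadjusted p under 0.05). Mitosis genes were lower with lncRNA-OIS1 hairpins than with p53 knockdown (median −0.94, 38 of 38 below 0, adjusted p = 3.38e-16, and 0.635 with an estimated correlation), and so were the replication and E2F targets (−0.68, 6.63e-09, and 0.635 with an estimated correlation). The p53 targets were higher (median 0.75, 8 members adjusted over the list alone and 19 without replicate 4, adjusted p = 1.05e-11, and 0.583 with an estimated correlation), as were lysosome genes (0.47, 3 members adjusted over the list alone and 7 without replicate 4, 6.63e-09, and 0.512 with an estimated correlation). Also higher were proteases and growth factors (0.57, 0.00062, and 0.583 with an estimated correlation), interferon (0.32, 0.00349, and 0.635 with an estimated correlation), matrix (0.23, 0.00968, and 0.635 with an estimated correlation) and inflammatory genes (1.19, 0.0499, and 0.635 with an estimated correlation). Cholesterol synthesis (−0.36, 0.00523, and 0.635 with an estimated correlation) and glycolysis (−0.34, 0.0499, and 0.635 with an estimated correlation) were lower.

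Against BRD7 knockdown the called gene was BRD7, 6.89-fold higher (log2 2.78, SE 0.14, adjusted p = 0.0197; 342 genes at an unadjusted p under 0.05). Interferon genes (median −0.48, adjusted p = 8.33e-08, and 0.914 with an estimated correlation) and mitosis genes (−0.38, 3.24e-07, and 0.915 with an estimated correlation) were lower with lncRNA-OIS1 hairpins than with BRD7 knockdown, followed by replication and E2F targets (−0.21, 0.00215, and 0.976 with an estimated correlation), contractile genes (−0.30, 0.0154, and 0.915 with an estimated correlation) and matrix genes (−0.28, 0.0273, and 0.915 with an estimated correlation). Neither contractile genes (−0.10, adjusted p = 0.0748) nor matrix genes (−0.12, 0.11) passed without replicate 4. RAS-MAPK output (0.26, 0.00121, and 0.64 with an estimated correlation) and proteases and growth factors (0.21, 0.0444, and 0.915 with an estimated correlation) were higher, and the latter did not pass without replicate 4 (0.31, adjusted p = 0.0562). No members of the lists called in these 2 comparisons were called over all genes, and without replicate 4 this was 1 inflammatory factor, against p53 knockdown. With no filter the counts were 68 and 23, with 46 and 19 of them genes that the filter removes. Against p53 knockdown the count was 0 without lncRNA-OIS1 replicate 1 or 2 and 31 without replicate 4. Against BRD7 knockdown, BRD7 was not called without any 1 of the senescent or lncRNA-OIS1 libraries, and the 1 gene then called without replicate 4 was ENSG00000217801.

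Changes against the senescent libraries were related between the 3 knockdowns. Across 12481 genes, changes with lncRNA-OIS1 and p53 knockdown against the senescent libraries correlated at r = 0.769, those with lncRNA-OIS1 and BRD7 knockdown at 0.755, and those with p53 and BRD7 knockdown at 0.693. All 3 comparisons share the senescent libraries, and unchanged groups simulated against them gave r of 0.468, 0.47 and 0.328. The covariances were 0.27, 0.187 and 0.258 against simulated values of 0.0648, 0.0654 and 0.0644, which leaves 0.205, 0.121 and 0.193. With a different senescent library as reference for each knockdown, r was 0.698 or 0.737, 0.674 or 0.695, and 0.658 or 0.636. The senescent libraries correlated at 0.996, and whatever is common to them enters every knockdown comparison. Neither the simulation nor the separate references can part related knockdown effects from such a shared difference.

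The last comparisons asked how far the knockdown libraries stood from the control. Of the 1878 genes that differed between senescent and control libraries, 80.4% were counted as moved back toward control with lncRNA-OIS1 knockdown. The shares were 74.9% with p53 knockdown and 80.5% with BRD7 knockdown. Genes at the floor in senescent and knockdown libraries alike, such as SULF1 and ANO3, did not move but could enter these shares. Taken 1 at a time, the lncRNA-OIS1 libraries gave 69.5% to 73.6%. For genes lower in senescent libraries they gave 61.2% to 65%, against 78% for the group. Simulations with no knockdown effect gave 59.8%, 56.6% and 56.6% for the lncRNA-OIS1, p53 and BRD7 groups. The moves were small: for the 992 genes higher in senescent libraries the medians were −0.30, −0.33 and −0.32 on the log2 scale, against a median rise of 1.07, and for the 886 lower genes 0.22, 0.25 and 0.21 against −1.41. The group shares were lower when the genes were called from 1 senescent library and the other served as the reference. Then 124 or 137 genes gave 34.7% or 39.4% for lncRNA-OIS1, 41.9% or 42.3% for p53 and 34.7% or 35% for BRD7. With as many genes as before, 1878, picked by size from 1 senescent library, an analysis added after the data were seen, the shares were 70.2% or 68.9%, 67.4% or 67.3%, and 67.4% or 66.2%.

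The lncRNA-OIS1 libraries were also set directly against the control, the same single library as in the senescent comparison, so anything peculiar to it enters both. MMP1 was 244-fold higher (log2 7.93, adjusted p = 0.00608), followed by STC1, TRPA1, TM4SF1, DOCK4, PKIA, TMEM158, SERPINB2, the protease-activated receptor gene F2RL1 and the hyaluronan synthase gene HAS2. ALDH1A1 fell by 7.73, followed by SULF1, SYPL2, ANO3, PREX2, OLR1, CHRM2, RNF150, EFHD1 and FAM65B, of which SULF1, ANO3, PREX2, RNF150 and EFHD1 were at the floor in all 4 lncRNA-OIS1 libraries. RAS-MAPK output had 13 of 24 members higher (14 adjusted over the list alone; median 1.65, adjusted p = 2.2e-08, and 0.132 with an estimated correlation), and p53 targets 9 of 34 (12 higher and 1 lower adjusted over the list alone; 0.91, 6.23e-05, and 0.559 with an estimated correlation). Matrix genes had 11 of 31 lower (15 adjusted over the list alone; −1.37, 2.23e-07, and 0.316 with an estimated correlation), and contractile genes 8 of 15 (10 adjusted over the list alone; −2.01, 2.2e-08, and 0.305 with an estimated correlation). The mitosis list, with a median of 0.36 (adjusted p = 0.14), the replication and E2F list at −0.02 (0.705) and the interferon list at −0.17 (0.379) were not called against the control. Lysosome genes were lower (1 higher and 4 lower over all genes, 1 and 6 adjusted over the list alone; −0.34, 0.00768, and 0.559 with an estimated correlation), and unfolded protein response (5 higher, 5 and 1 adjusted over the list alone; 0.36, 0.0272, and 0.559 with an estimated correlation) and glycolysis genes (1 higher, 1 adjusted over the list alone; 0.41, 0.0272, and 0.559 with an estimated correlation) were higher. Without replicate 4 the last 2 lists did not pass (adjusted p = 0.0746 each) and inflammatory factors did (median 1.41, adjusted p = 0.0165, and 0.764 with an estimated correlation). In that fit 16 p53 targets were called higher and 1 lower, 6 inflammatory factors higher and 1 lower, and 3 glycolysis genes higher. The lysosome list had 1 higher and 9 lower, and the unfolded protein response list 5 higher and 3 lower (median 0.39). In total 1399 genes changed, 671 higher and 728 lower, a balance that turned with the filter on the mean (672 and 545) and without replicate 4 (1448 and 1374). The count was 400 or 397 without senescent replicate 1 or 2, 800 without lncRNA-OIS1 replicate 2 and 2822 without replicate 4.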

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

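Of the tests in this part, the one on transcript length was written before its result was seen, and the other tests of explanations were chosen after.

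Among the 4 lncRNA-OIS1 libraries, replicate 4 lay far from the other 3. For the number of genes over 2-fold above every other library (300, against 20, 0 and 27), its gap to the nearest library made up 0.91 of the range, and for the number over 2-fold below (224, against 2, 2 and 11) it made up 0.959. Among 101 named genes checked in the same way, 9 had 1 library apart, where chance alone gives about 1 in 20, and replicate 4 was that library in 7 of them. The genes and their ratios were CDKN2A (1), TGFB2 (1), LMOD1 (1), LINC00973 (0.903), FAM65B (0.879), HAS2 (0.869) and CDKN1B (0.858). For GLB1 (0.902) replicate 1 was apart, at 1094.2 against 1022.8 to 1029.6, and for INSIG1 (0.928) replicate 2, at 1715.9 against 2461.8 to 2531.7. A ratio of 1 means that the other 3 libraries were all at the floor.

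What set replicate 4 apart was weighed against 3 explanations. A small admixture of RNA from other cells would leave abundant transcripts of the main cells near their level. Of 7304 genes with at least 200 in each of the other 8 libraries, 8 lay under one eighth of the lowest of them in replicate 4, among them AEBP1 (35 against 1057.8), INA (20 against 553.4) and NDN (20 against 500), and the other 7 RAS libraries had at most 1 such gene. This argues against a small admixture as the whole cause, with the reservation that the bound was first set at 10 or more genes and was lowered after the count of 8 had been seen. By the first bound the test would not have argued against it. A swap with the BRD7 knockdown library is argued against by BRD7 at 112% of the senescent mean in replicate 4, since the library labelled as that knockdown had 16.2%. A library of other cells under this label and an effect of this hairpin that the other 3 hairpins lack cannot be told apart, because the hairpin has 1 library. The highest correlation of replicate 4 with another library across genes was 0.942, with the p53 knockdown library.

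Mitosis and DNA replication genes were higher in all 6 knockdown libraries than in the senescent libraries. A trend with transcript length between libraries is argued against as the whole cause: the length trend was weak (Spearman rho 0.122, 0.0464 and 0.141 for lncRNA-OIS1, p53 and BRD7 knockdown), and after its removal the 6 list medians kept at least 0.968 of their size. A senescent reference that was low in 1 library is argued against too, since the smallest of the 12 library medians, each against the higher of the senescent libraries, was 0.507 on the log2 scale. In each knockdown library, 37 or 38 of 38 mitosis genes and 37 to 40 of 41 replication genes lay above both senescent libraries. A culture or library batch shared by the senescent libraries cannot be told apart from the knockdowns. These libraries correlated at 0.996, more than any other pair, and no library carries a batch label. Proliferation of some cells despite RAS activation after each knockdown stays open as a biological explanation that was not tested.

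Effects against the senescent libraries differed between knockdowns by a direct test for BRD7 (log2 2.78 for lncRNA-OIS1 against BRD7 knockdown, higher in 4 of 4 libraries, adjusted p = 0.0197). BRD7 is the gene that the other hairpin targets.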

How the results depend on the processing

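In this part, the tests of the lists without replicate 4 and with median-of-ratios scaling, the reversal with libraries left out or with genes picked by size, and the lncRNA-OIS1 comparisons with p53 knockdown, BRD7 knockdown or control without a senescent replicate were chosen after the data were seen. Where no cause is given below, the cause was not tested. A comparison left with 1 senescent library assumes that it varies like the other groups.

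The 1878 genes changed, senescent against control, ranged from 1733 to 2042 over the pseudocounts, filters, scaling and variance models, and 1221 were also at least 2-fold. Leaving out 1 library gave 124 (without senescent replicate 2) to 3704 (without lncRNA-OIS1 replicate 4). For lncRNA-OIS1 knockdown against senescent the count of 0 by limma (2805 at an unadjusted p under 0.05) became 57 with no filter, 16 of them genes that the filter removes, and 1 (SOCS1) for eBayes without trend. Leaving out 1 library gave 0 to 164 (without replicate 4). A planned replicate block on the numbers 1 and 2 joined unrelated hairpins, and no pairing showed (correlations −0.0713 and −0.099). With 4 libraries and 1 residual degree of freedom it gave 0 (2778 at an unadjusted p under 0.05), which says nothing about stability. For p53 knockdown the 479 genes became 2, among them NAALADL2, for eBayes without trend, and leaving out 1 library gave 0 to 2146 (without replicate 4). For BRD7 knockdown the 1 gene became 0 with pseudocount 10, 0 with pseudocount 50, 0 for eBayes without trend and 30 with no filter, and 0 to 8 (without replicate 4) when 1 library was left out.

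For lncRNA-OIS1 against p53 knockdown, 1 gene became 68 with no filter, and 0 to 31 (without replicate 4) with 1 library left out. For lncRNA-OIS1 against BRD7 knockdown, 1 became 23 with no filter, and 0 to 1 with 1 library left out, where the 1 without replicate 4 was another gene. Against control the 1399 genes ranged from 397 (without senescent replicate 2) to 2822 (without replicate 4).

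The share of RAS-changed genes counted as moved back toward control was not stable. Called from senescent replicate 1 with replicate 2 as reference, or the other way round, it was 34.7% and 39.4% for lncRNA-OIS1 knockdown, 41.9% and 42.3% for p53 knockdown, and 34.7% and 35% for BRD7 knockdown. With as many genes picked by size it was 70.2% and 68.9%, 67.4% and 67.3%, and 67.4% and 66.2%. With 1 library left out, the ranges were 37.2% (without senescent replicate 1) to 80% for the reversal of the RAS effect: lncRNA-OIS1 knockdown against senescent, 39.5% to 76.1% for the reversal of the RAS effect: p53 knockdown against senescent, and 32.3% to 80.7% for the reversal of the RAS effect: BRD7 knockdown against senescent (both lowest without senescent replicate 2). The share thus depended on which genes were taken. A low share need not mean that the other genes moved the other way, since genes at the floor in senescent and knockdown libraries did not move. Why the share was lower among the fewer genes called with 1 senescent library was not tested.

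Of 104 gene calls named in the report, pseudocounts of 10 and 50 lost 3 and 7, no filter 10, eBayes without trend 30, and median-of-ratios scaling and robust moderation 0. Leaving out either senescent library lost 72, lncRNA-OIS1 replicates 1 to 3 lost 42, 43 and 39, and replicate 4 lost 1 and gained 52. Direction turned for genes that were not called. The log2 change of IL1A, lncRNA-OIS1 knockdown against senescent, was 0.023 with pseudocount 50. With 1 library left out, log2 changes ranged from −0.173 to 0.055 for BRD7, senescent against control. For lncRNA-OIS1 knockdown they ranged from −0.556 to 0.453 for IL1A, and from −0.265 to 2.49 for IL1B, lncRNA-OIS1 knockdown against senescent. They were −1.106 to 0.012 for IL8, p53 knockdown against senescent, and −0.686 to 0.322 for IL1A, BRD7 knockdown against senescent.

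For the lists, all 32 calls among 68 list tests (senescent against control, and each knockdown against senescent) were lost with an estimated correlation between genes (lowest adjusted p = 0.285). With median-of-ratios scaling 1 was lost (unfolded protein response, lncRNA-OIS1 knockdown), and without replicate 4, 1 was lost and 2 gained. No called list turned. Some lists that were not called did turn without replicate 4. With lncRNA-OIS1 knockdown against senescent, the glycolysis median went from 0.034 to −0.008 and the leukocyte median from −0.028 to 0.225. The test of inflammatory factors, senescent against control, then pointed up. Of these comparisons, replicate 4 enters the log2 changes of lncRNA-OIS1 knockdown alone, so the list medians of the others could not turn. In the other comparisons, without replicate 4, the contractile, matrix and protease calls against BRD7 knockdown and the unfolded protein response and glycolysis calls against control were lost, and inflammatory factors against control were gained. Depth per library is unknown, so what it limits cannot be given.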

Other observations

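The histone genes described here were chosen after their values were seen, and no explanation was tested for them. Of 11 histone genes tested, 8 were lower in all 6 knockdown libraries than in both senescent libraries and 0 were higher, and 9 were lower in the control than in both senescent libraries. Among all 12481 genes, 18.6% were lower and 14.7% higher in all 6 knockdown libraries than in both senescent libraries. Exchangeable libraries with no difference would give 3.57% in each direction. The senescent libraries resembled each other more than any other pair (r = 0.996), so higher shares could arise with no knockdown effect. HIST1H2BK stood at 315.7 in the control, 1132.4 and 1296.3 in the senescent libraries, 392.9 to 578.9 with lncRNA-OIS1 hairpins, 261.7 with p53 knockdown and 389.9 with BRD7 knockdown. HIST1H4H stood at 24, 233.1 and 245.8, 58.7 to 95.8, 46.2 and 81.3 in the same order. Histone genes resemble each other in sequence, and how reads shared between them were counted is not given in the sources used here. The libraries hold polyA RNA, so these values cover polyadenylated histone transcripts and not total histone RNA.

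MMP1 had the highest value of the table, 211606.6, in lncRNA-OIS1 replicate 4. HRAS stood at 26556.6 in the control and 23342.7 in the p53 knockdown library, and between 11321.3 and 19543.6 in the other 7.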
